A study of Arabidopsis thaliana with 6 samples.

How the data were processed

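RNA from roots of Arabidopsis thaliana seedlings was measured on 1-colour microarrays in 6 samples, 3 of the axs1-1 axs2-1/+ mutant and 3 of the wild type Col-0. Per the labels, seedlings grew on vertical plates of MS medium in long days, roots were cut at day 12, about 30 roots were pooled for each biological replicate, and total RNA was copied into cRNA labelled with the dye Cy3. The labels do not say whether the 3 pools of a genotype came from separate plates or sowings, so p-values measure the spread between these pools.

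Per the file headers, the arrays were read with Agilent Feature Extraction 10.7.1.1, which gives each spot a mean brightness, a local background and a processed signal. The processed signal is an intensity after background subtraction with spatial detrending and multiplicative detrending, per the file headers. The deposited value table holds log2 values of the same arrays. Its 6 columns contain one and the same set of sorted values with a median of 9.183, which is what quantile normalization gives. Each column correlated with that array's log2 processed signal across probes at r = 0.9987 to 0.9999, which settles scale and direction. The authors' further steps are not given in the sources used here.

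Each array held 43803 probe spots of 43603 probes and 1417 control spots, which were left out. Between 72.2% and 77.5% of probe spots were well above background, 18 to 50 spots per array were flagged as outliers and left out, and 0 were saturated. The 75th percentile of the processed signal lay between 2507.7 and 4448.3. The number of arrays limits the precision. Probe names were updated through a table of assembly TAIR10.1, which matched 34358 probes by accession and 1880 by the locus in their name. Another 7365 probes kept the name in the file. The files name another build than that table, so no coordinates are printed.

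The log2 processed signal minus the array's 75th percentile was the measure. Spots of a probe were averaged. Probes well above background on at least 3 of 6 arrays were kept, 32965 in all, and each gene was represented by its probe with the brightest mean. This left 24306 genes, 21076 with a locus and 3230 known by the file's name. Of the 6627 genes with more than 1 kept probe, 1 had probes called in opposite directions. Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend), and p-values were adjusted by Benjamini-Hochberg over all genes with a threshold of 0.05. Differences are mutant minus wild type. Where every array of a group was not well above background, the fold is given as a lower bound. This bound holds for the processed signal only, and another background correction can give a smaller fold. It sets the brighter group's mean against the dim group's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background.

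The analysis of gene groups used 33 lists fixed before the data were examined, of which 25 were named member by member and 8 were families taken by words of the annotation. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Camera compares a list with the other genes, and fry tests whether its members move one way. The rule for named genes was also fixed then. It took AXS1, AXS2, BOR1 and NIP5;1, the 6 largest rises and 6 largest falls among called genes whose groups did not overlap, that were above background on all arrays of a group and had a symbol or a described function, and up to 2 called members of each list with the largest change.

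The arrays lay on 2 slides, each scanned on its own occasion. Slide 1 held replicate 1 of both genotypes and slide 2 held replicates 2 and 3. Both slides hold as many mutant as wild-type arrays, so a block for slide leaves each log2 difference as it is and changes the test. Replicate numbers come from the labels. Deviations of same-numbered arrays from their group means correlated across genes at 0.52, 0.29 and 0.28, so the numbers may pair the arrays. Replicates 2 and 3 of opposite genotypes correlated at 0.20, so the shared slide is part of this pairing. The main fit used neither pairing nor slide. Its p-values and counts treat the groups as unpaired, and blocks for replicate and for slide were run as alternatives.

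Alternatives covered background correction by normexp with an offset of 50, quantile normalization, median centring, the deposited value table, 2 other filters on dim probes, the mean of a gene's probes, no intensity trend, array weights, blocks for replicate, slide and scan, unmoderated variances, and each array left out in turn. After the data were seen, 2 more were added: the slide 2 arrays alone, and normexp with outlying local backgrounds replaced. The planned normexp fit was distorted on wild-type replicate 3. A local background of 73652.5 there, against a median of 26, pulled the fitted background mean to -872.7. A call gained or lost only under normexp as planned cannot be told from an effect of that fit. The test was checked on simulated arrays of this comparison, drawn for 24306 genes with 200 changed. It recovered 32.8% of the genes changed 1.5-fold, 73.1% of those changed 2-fold and 89.4% of those changed 4-fold, with 5 false calls. The simulated spread was independent between genes and arrays, without deviations shared by a slide. Far fewer genes were changed than the 22.3% called in the data. These rates may therefore not carry over to the comparison. Tables and plots were made with Python 3.11.15.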

Results

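Root transcripts of the axs1-1 axs2-1/+ mutant were compared with those of wild-type Col-0 in 3 pools of roots each. AXS1 and AXS2 encode UDP-D-apiose/UDP-D-xylose synthases, which make the donor of apiose, a sugar of the pectin rhamnogalacturonan II that borate cross-links in the wall. The notation marks axs1-1 as homozygous and axs2-1 as heterozygous. The comparison asks which root transcripts differ when most of this enzyme's gene copies are mutated. The 75th percentile of the processed signal was 4448.3, 2877.5 and 3200.8 on the mutant arrays and 4293.5, 2914.7 and 2507.7 on the wild-type arrays.

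The AXS1 transcript was nearly absent from the mutant and AXS2 was reduced. AXS1 (AT2G27860) was 242-fold lower, at a log2 level of -6.40 ± 0.22 (SD, n = 3) in the mutant and 1.52 ± 0.064 (SD, n = 3) in the wild type, and its probe was still well above background on 2 of the 3 mutant arrays. AXS2 (AT1G08200) was 1.84-fold lower, at 2.15 ± 0.11 (SD, n = 3) against 3.03 ± 0.11 (SD, n = 3). The log2 differences were -7.92 (SE 0.13, limma adjusted p = 8.14e-07) and -0.88 (SE 0.089, adjusted p = 0.000774). Within slide 1 and slide 2 they were -8.08 and -7.84 for AXS1, and -1.09 and -0.77 for AXS2. The AXS1 difference was -6.32 under normexp as planned and -6.39 with outlying local backgrounds replaced, so its fold depends on the background correction. Each gene had 1 probe. Where the lesions lie relative to the probes is not given in the sources used here, so the values describe the probed part of each transcript.

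**Figure D1:**
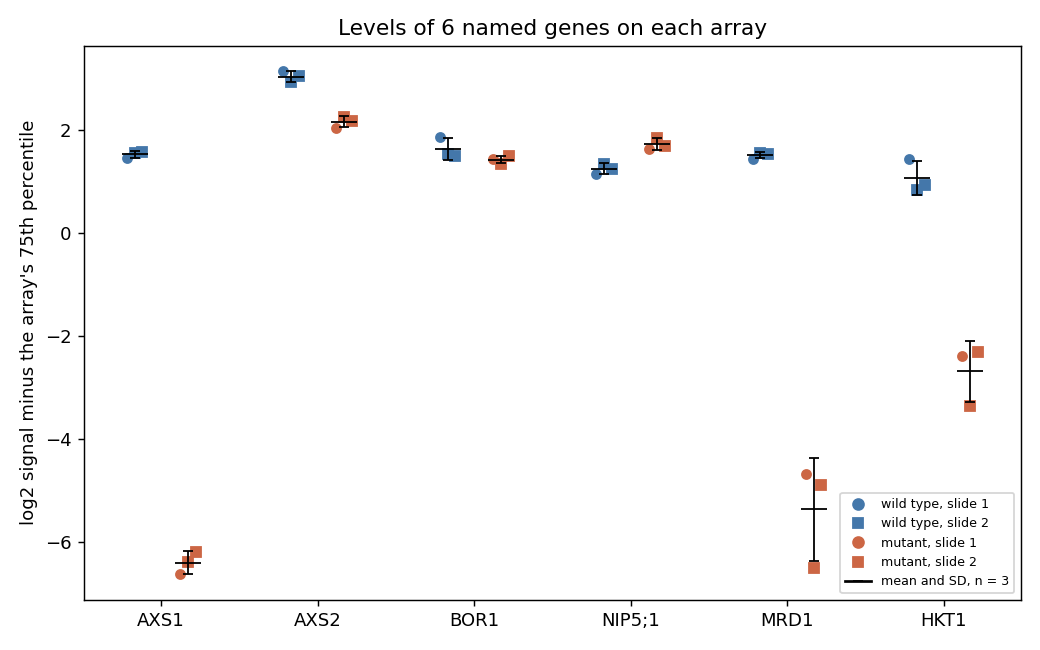
Log2 signal minus the array's 75th percentile (vertical axis) of 6 named genes on each of the 6 arrays, with circles for slide 1, squares for slide 2, and bars for the mean and SD of 3 arrays. AXS1 lies at 1.52 in the wild type and -6.40 in the mutant, AXS2 moves by a log2 difference of -0.88, and the groups of BOR1 overlap.

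Of 24306 genes tested, 2736 were higher and 2696 lower in the mutant (limma, adjusted p under 0.05). By at least 2-fold, 916 were higher and 618 lower. Centring each array on its median instead gave 1861 higher and 3399 lower, and it moved the median difference of all genes from 0.032 to -0.069 on the log2 scale, so small changes depend on the scaling. With slide as a block the counts were 3940 higher and 3829 lower, and on slide 2 alone 3707 and 3321, with 4958 of the 5432 calls made there too in the same direction. Over all genes, the slide 1 and slide 2 differences correlated at 0.752, across genes and not across independent replicates. The groups did not overlap for 9811 genes, 40.4% of those tested, where chance gives 10% for 3 against 3. The counts fell by more than 1.5 times without mutant replicate 2 (1720 higher, 1777 lower), wild-type replicate 2 (1641 and 1561) or wild-type replicate 3 (1652 and 1701).

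**Figure D2:**
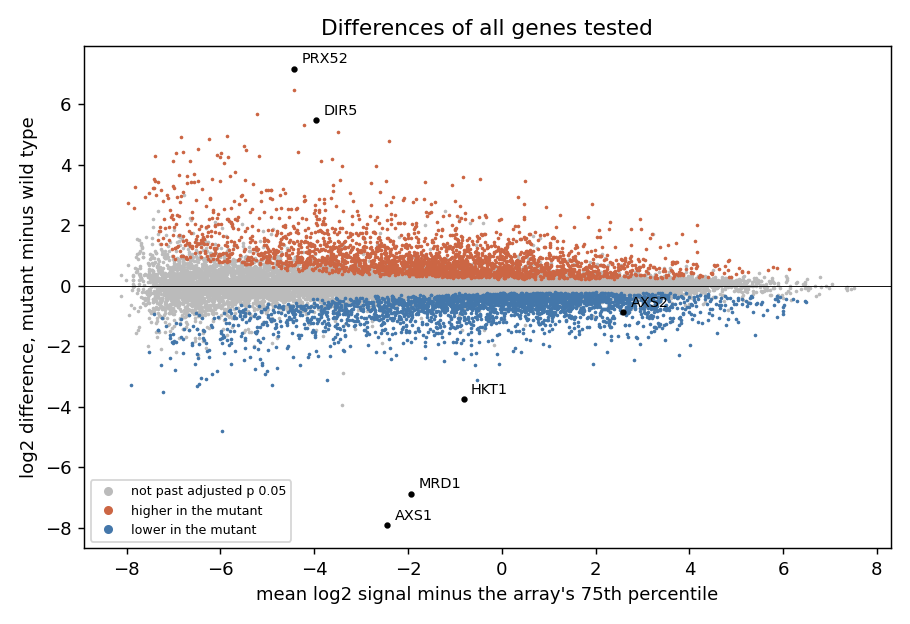
Log2 difference, mutant minus wild type (vertical axis), against the mean log2 signal relative to the 75th percentile (horizontal axis) for all 24306 genes, coloured by whether limma called them higher, lower or neither. The 2736 higher and 2696 lower genes spread over the whole range of signal, with AXS1 and MRD1 the farthest below 0 and PRX52 the farthest above.

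The largest rises by the naming rule were those of PRX52, AT3G28510, AT3G47480, DIR5, ENDO2 and scpl30. PRX52 (AT5G05340), a class III peroxidase, was at least 86.2-fold higher, its probe not well above background on any wild-type array (fitted log2 difference 7.17, adjusted p = 8.24e-05). AT3G28510, of the AAA-type ATPases, rose by a log2 difference of 6.48 and was above background on 1 of 3 wild-type arrays. AT3G47480, a calcium-binding EF hand protein, was at least 29.4-fold higher (adjusted p = 0.000136). DIR5, a dirigent protein, rose by a log2 difference of 5.465 (SE 0.58), with 4.11 and 6.14 on slides 1 and 2 and 4.84 without mutant replicate 3. The endonuclease gene ENDO2, above background on 2 of 3 wild-type arrays, rose by 5.32 (SE 0.51), with 4.09 and 5.94 on the slides and 5.98 without wild-type replicate 1. The serine carboxypeptidase-like gene scpl30 rose by 5.09 (SE 0.40), with 3.88 and 5.69 on the slides. After AXS1, the largest fall was that of MRD1 (AT1G53480), of unknown function, with a log2 difference of -6.87 (SE 0.43, adjusted p = 0.000219) and values of -6.12 and -7.24 on the slides. HKT1, which encodes a sodium transporter, fell by 3.75 on the log2 scale (adjusted p = 0.000348). The other large falls were in genes not well above background on any mutant array: scpl33 was at least 3.70-fold lower, AT2G44920, a thylakoid lumenal protein, at least 5.80-fold lower, and AT5G50060, of the pectin methylesterase inhibitor family, at least 2.15-fold lower. Normexp adds an offset, which can shrink the differences of dim genes but was not tested on its own. As planned it gave log2 differences of 3.34 for PRX52, 2.86 for AT3G28510, 2.72 for DIR5, 2.16 for ENDO2 and 2.90 for scpl30, and with outlying local backgrounds replaced 4.35, 3.88, 3.71, 3.21 and 3.81. As planned it ended the calls of AT3G47480 (adjusted p = 0.157), scpl33 (0.646), AT2G44920 (0.444) and AT5G50060 (0.722), which held with those backgrounds replaced (0.00025, 0.011, 0.00105 and 0.0348). Their log2 differences with those backgrounds replaced were 2.84, -1.105, -1.37 and -0.835. These and that of PRX52 are smaller than the lower bounds above, which hold for the processed signal only.

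Over all genes tested, 22.3% were called. Of 38 measured genes of nucleotide sugar interconversion, 5 were higher and 3 lower, the same numbers as when adjusted over the list alone, and the list did not stand apart (camera adjusted p = 0.757). Besides AXS1, the largest change was in UGE3, a UDP-glucose epimerase, at -1.13. Of 23 pectin synthesis genes, 2 were higher and 1 lower (2 and 0 when adjusted over the list alone, camera adjusted p = 0.435); GAUT15 was higher by 0.74 and ARAD2 by 0.68, and both calls ended under normexp as planned (0.057 and 0.31) and held with outlying local backgrounds replaced (0.60 and 0.62). Among 9 boron transport genes 3 were higher and 2 lower, the same numbers when adjusted over the list alone. In camera the list did not stand apart (adjusted p = 0.634) except under normexp as planned (0.037), whose fit was distorted on wild-type replicate 3. Fry in the main fit called the list higher (adjusted p = 0.00888). Its median was 0.053, and below 0 under each scaling alternative (-0.033 to -0.19). BOR2 (AT3G62270), a borate exporter, was higher by 1.87 (SE 0.11, adjusted p = 0.000178) and NIP5;1, a boric acid channel, by 0.48 (SE 0.089, adjusted p = 0.00843). BOR5, above background on 2 of 3 arrays in each group, was lower by a log2 difference of -1.46 (adjusted p = 0.0378), a call lost when any array except wild-type replicate 1 was left out (-1.12 to -1.63), under quantile normalization (adjusted p = 0.0519), without a filter on dim probes (0.0537) and under both forms of normexp (0.729 as planned). BOR1 differed by -0.21 (adjusted p = 0.238), and its other probe by 0.26.

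The cell wall lists were mixed. Of 29 expansin and xyloglucan endotransglucosylase genes, 9 were higher and 4 lower (11 and 6 when adjusted over the list alone). EXPA8 rose by 2.41 and TCH4, a touch-inducible xyloglucan endotransglucosylase, by 2.31 on the log2 scale. The list's median was 0.25, with 0.18 and 0.27 on slides 1 and 2, and its camera adjusted p was 0.0876. It passed under each scaling alternative, among them quantile normalization (0.0412), median centring (0.0281) and normexp as planned (0.000304), and without a filter on dim probes (0.0455), but not with slide as a block (0.166) or an estimated correlation (0.711). None of 10 genes of primary wall cellulose synthesis passed (0 over all genes and 0 when adjusted over the list alone; camera adjusted p = 0.711). Of 19 genes of the secondary wall and xylem, 1 was higher and 1 lower (0 and 0 when adjusted over the list alone, camera adjusted p = 0.852), namely NAC101 (VND6) at 0.49 and FRA8 at -0.51. NAC101 lost its call without any 1 array other than mutant replicate 1 (0.41 to 0.55), and FRA8 without mutant replicate 2 (-0.54), wild-type replicate 1 (-0.44) or wild-type replicate 2 (-0.52). Both also lost it under normexp as planned (NAC101 -0.31, adjusted p = 0.8, and FRA8 -0.36, adjusted p = 0.117). With outlying local backgrounds replaced neither passed (0.33, adjusted p = 0.138, and -0.44, adjusted p = 0.132). Of 10 wall receptors and their peptides, 1 fell, the peptide gene RALF1 at -0.76 (1 when adjusted over the list alone, camera adjusted p = 0.240).

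The wall families taken from the annotation held large changes in both directions. Of 73 pectin methylesterases and their inhibitors, 14 were higher and 11 lower (17 and 12 when adjusted over the list alone, camera adjusted p = 0.653), with AT3G47380 at 2.66. Among 59 polygalacturonases and pectate lyases, 11 were higher and 6 lower (11 and 6 when adjusted over the list alone, camera adjusted p = 0.634), with the pectate lyase AT3G27400 at 2.30 and the polygalacturonase AT1G05650 at -1.74, a call lost under normexp as planned at about the same difference (-1.71, adjusted p = 0.527). Extensins and proline-rich proteins gave 17 higher and 16 lower of 158 (17 and 15 when adjusted over the list alone, camera adjusted p = 0.772), with AT5G07570 at 2.67 and AT3G03776 at -2.07, both past no threshold under normexp as planned (0.96, adjusted p = 0.473, and -2.03, adjusted p = 0.169). With outlying local backgrounds replaced, the calls of AT1G05650 (-1.04), AT5G07570 (1.85) and AT3G03776 (-1.47) held. Arabinogalactan proteins gave 6 higher and 5 lower of 43 (8 and 5 when adjusted over the list alone, camera adjusted p = 0.994), with FLA5, above background on 2 of 3 wild-type arrays, at 1.86 and AT4G16980 at -2.42.

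Class III peroxidases changed in 36 of 67 members, 24 higher and 12 lower (28 and 15 when adjusted over the list alone). Besides PRX52, the peroxidase gene AT1G14550 was at least 10.2-fold higher. The family was taken by annotation words and holds BGAL1 and NRPD2A, whose symbols are those of other proteins, both among the called members. The peroxidase median was 0.30, with 0.063 on slide 1, 0.37 on slide 2, 0.18 under normexp as planned and 0.13 without a filter on dim probes (camera adjusted p = 0.0410, and adjusted p = 0.711 with an estimated correlation). Its call ended with slide as a block (adjusted p = 0.147), with a block for replicate (0.134), with probes above background on all 6 arrays (0.0855), and without mutant replicate 2 (0.0809), mutant replicate 3 (0.0516) or wild-type replicate 1 (0.0684). Of 17 genes of phenylpropanoid and lignin synthesis, 5 were higher and 0 lower, as when adjusted over the list alone, among them CCR2 at 1.46 and 4CL2 at 0.57. The median was 0.19, those on slides 1 and 2 were 0.070 and 0.25, and that under normexp as planned 0.31 (camera adjusted p = 0.0291, and adjusted p = 0.711 with an estimated correlation). The call ended under median centring (0.0563), with the replicate block (0.0532), without mutant replicate 2 (0.0991) and without wild-type replicate 3 (0.0775).

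Of 18 genes of jasmonate synthesis and response, 11 were higher and 1 lower (13 and 1 when adjusted over the list alone). AOC2, an allene oxide cyclase of jasmonate synthesis, was above background on 2 of 3 wild-type arrays and rose by 2.68 (SE 0.30), and the response repressor JAZ10 rose by 2.65 (SE 0.29), or 1.60 under normexp as planned. The median was 0.64, with 0.51 and 0.71 on slides 1 and 2 and 0.30 under normexp as planned (camera adjusted p = 9.14e-05, and adjusted p = 0.351 with an estimated correlation). Of 20 genes of salicylate and pathogen defence, 11 were higher and 3 lower (11 and 3 when adjusted over the list alone). PAD3, the last enzyme of camalexin synthesis, rose by 3.09 (SE 0.21), or 1.89 under normexp as planned, and PBS3, which acts in salicylate synthesis, by 3.61 (SE 0.75), its probes ranging from 1.90 to 3.61 and the probe used above background on 2 of 3 wild-type arrays. On slide 2 alone PBS3 missed the threshold (2.93, adjusted p = 0.0632). The list's median was 0.72, with 0.69 and 0.67 on slides 1 and 2 and 0.13 under normexp as planned (camera adjusted p = 0.00500, and adjusted p = 0.351 with an estimated correlation).

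Of 16 genes of reactive oxygen production and scavenging, 5 were higher and 1 lower (5 and 1 when adjusted over the list alone), led by the glutathione S-transferase genes GSTU25 at 2.35 and GSTU24 at 1.33. The median was 0.24, with 0.17 and 0.29 on slides 1 and 2 and 0.14 under median centring (camera adjusted p = 0.0267, and adjusted p = 0.595 with an estimated correlation), and the call ended without mutant replicate 2 (0.0565). Of 44 glutathione S-transferases, 12 were higher and 6 lower (13 and 7 when adjusted over the list alone, camera adjusted p = 0.0631). GSTU11 stood at 4.50 and was above background on 1 of 3 wild-type arrays, and GSTU12 stood at 4.19, or 2.23 under normexp as planned. The list passed under quantile normalization (0.0114) and normexp as planned (0.000304), without a filter on dim probes (0.0190), with the mean of a gene's probes (0.0492), and without mutant replicate 3 (0.0250) or wild-type replicate 2 (0.0175), but not with slide as a block (0.118) or an estimated correlation (0.711). Heat shock proteins gave 17 higher and 12 lower of 163 (15 and 12 when adjusted over the list alone, camera adjusted p = 0.435). HSP23.6-MITO and HSP17.6A were each above background on 2 of 3 wild-type arrays. HSP23.6-MITO at 3.49 lost its call without mutant replicate 2 (2.97) or 3 (3.11), and HSP17.6A at 3.16 without mutant replicate 2 (2.61) or 3 (2.83) or wild-type replicate 1 (2.49) or 3 (3.37). Both calls also ended under normexp as planned (0.73 and 0.75, each adjusted p = 0.729). With outlying local backgrounds replaced, both stood at 1.72 and missed the threshold (adjusted p = 0.057 and 0.0586). Of 15 glucosinolate synthesis genes, 6 were higher and 1 lower (6 and 2 when adjusted over the list alone, camera adjusted p = 0.222), with UGT74B1 at 0.60 and CYP79B3 at -1.06, and medians of opposite sign on slides 1 and 2, -0.25 and 0.42. The list passed without mutant replicate 1 (0.0347) and on slide 2 alone (0.0425), but not with slide as a block (0.323) or an estimated correlation (0.711).

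Of 24 genes of auxin transport and response, 9 were higher and 2 lower (10 and 2 when adjusted over the list alone), with IAA5 at 1.13 on the log2 scale and the auxin exporter gene PIN7 2.14-fold higher. The median was 0.28, with 0.20 and 0.33 on slides 1 and 2, 0.070 under normexp as planned and 0.18 under median centring (camera adjusted p = 0.0164, and adjusted p = 0.711 with an estimated correlation). The call ended without mutant replicate 2 (0.0565). Of 15 genes of abscisate and water stress response, 1 was higher and 5 lower (1 and 8 when adjusted over the list alone), among them ABI1, a phosphatase of abscisate signalling, at -0.77. The higher gene, RD22 at 1.04, lost its call without mutant replicate 3 (0.96) or wild-type replicate 2 (0.94), and its adjusted p on slide 2 alone was 0.0619. The list's median was -0.30, with -0.13 and -0.60 on slides 1 and 2 and -0.49 without mutant replicate 1 (camera adjusted p = 0.0267, and adjusted p = 0.711 with an estimated correlation). The call ended under median centring (0.0563) and without mutant replicate 2 (0.0549) or wild-type replicate 3 (0.0984). Of 17 cytokinin response genes, 4 were higher and 6 lower (6 and 7 when adjusted over the list alone, camera adjusted p = 0.521, but 0.0272 under normexp as planned), with the cytokinin oxidase gene CKX4 at -2.61 and the synthesis gene IPT5 at -1.77. Of 12 ethylene genes, 1 was higher (1 when adjusted over the list alone, camera adjusted p = 0.634), the synthesis gene ACS7 at 2.87.

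Water channel transcripts were mostly lower. Of 17 genes, 11 were lower and 2 higher (12 and 3 when adjusted over the list alone), with the tonoplast channel TIP2;3 at -1.95 (SE 0.18) and the plasma membrane channel PIP2;5 in the other direction at 2.87 (SE 0.26). The median was -0.50, with -0.39 and -0.54 on slides 1 and 2 and -0.34 under quantile normalization (camera adjusted p = 0.000636, and adjusted p = 0.351 with an estimated correlation). Of 20 genes of phosphate, nitrate and sulfate nutrition, 11 were higher and 2 lower (12 and 4 when adjusted over the list alone). The list also holds HAK5, a high-affinity potassium transporter, which showed its largest rise at 3.45 (SE 0.21), and the nitrate reductase gene NIA1 rose by 2.20 (SE 0.23). The median was 0.44, with 0.63 and 0.31 on slides 1 and 2 (camera adjusted p = 0.00339, and adjusted p = 0.549 with an estimated correlation). Of 16 iron genes, 4 were higher and 6 lower (4 and 8 when adjusted over the list alone, camera adjusted p = 0.173), with the nicotianamine synthase gene NAS2 at 2.28 and the iron-deficiency regulator BHLH100 at -2.78, which rests on values below background on 2 of 3 mutant arrays.

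Of 24 genes of the root meristem and cell division, 8 were higher and 0 lower, and 21 were higher when adjusted over the list alone. WOX5, expressed in the quiescent centre, rose by 1.20 (SE 0.22), a call lost under normexp as planned (0.12, adjusted p = 0.922) and with unmoderated variances (0.0613), and held with outlying local backgrounds replaced (0.84, adjusted p = 0.0118). The cytokinesis kinesin gene HIK rose by 0.90 (SE 0.20), a call lost without mutant replicate 3 (0.77), wild-type replicate 2 (0.76) or wild-type replicate 3 (0.85). The median was 0.51, with 0.20 and 0.67 on slides 1 and 2 and 0.22 under normexp as planned (camera adjusted p = 4.06e-05, and adjusted p = 0.711 with an estimated correlation). Of 18 genes of the endodermal barrier and suberin, 9 were higher and 1 lower (11 and 2 when adjusted over the list alone). FAR1, a fatty acyl reductase of suberin synthesis, rose by 1.70 (SE 0.19) and CASP5, a Casparian strip membrane protein, fell by 1.79 (SE 0.18). The median was 0.49, with 0.38 and 0.64 on slides 1 and 2 (camera adjusted p = 0.00339, and adjusted p = 0.711 with an estimated correlation). Of 13 phloem genes, 3 were higher and 0 lower (5 and 0 when adjusted over the list alone), with OPS at 1.16 and AT5G57130 at 1.32, which lost its call without mutant replicate 2 (1.38) or 3 (1.14). The phloem median was 0.60, with 0.34 and 0.54 on slides 1 and 2, -0.007 under normexp as planned and 0.24 with outlying local backgrounds replaced (camera adjusted p = 0.0461, and adjusted p = 0.792 with an estimated correlation). The call ended without mutant replicate 2 (0.149), mutant replicate 3 (0.120) or wild-type replicate 1 (0.293).

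Of 14 root hair genes, 1 was higher and 0 lower (0 and 0 when adjusted over the list alone). This was RHD6, a regulator of hair initiation, at 0.41, a call lost without mutant replicate 2 or 3 or wild-type replicate 1 or 2 (0.34 to 0.40). The call was also lost under normexp as planned (0.35, adjusted p = 0.222) and with outlying local backgrounds replaced (0.37, adjusted p = 0.0719). The root hair median was -0.37, with -0.73 and -0.17 on slides 1 and 2 (camera adjusted p = 0.123), and its test passed with slide as a block (0.0386) and without mutant replicate 2 (0.0371) or 3 (0.0263), while its adjusted p with an estimated correlation was 0.845. None of 5 root cap genes passed (0 when adjusted over the list alone, camera adjusted p = 0.634).

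Photosynthesis transcripts were lower. Of 20 genes, chosen as markers of shoot tissue, 18 were lower and 0 higher, and 20 were lower when adjusted over the list alone. GAPA, a chloroplast glyceraldehyde-3-phosphate dehydrogenase, fell by 1.60 (SE 0.19) and RCA, the Rubisco activase, by 1.45 (SE 0.082). The median was -1.05, with -0.81 and -1.14 on slides 1 and 2 (camera adjusted p = 1.61e-14, and adjusted p = 0.535 with an estimated correlation). Ribosomal proteins, a family meant as cytosolic but taken by annotation words, gave 2 higher and 14 lower of 295 (0 and 7 when adjusted over the list alone). The 2 largest falls were SSR16 at -0.81 and AT5G24490, annotated as a 30S protein, at -0.73, both of the bacterial type found in organelles. The ribosomal median was 0.13, with -0.014 and 0.19 on slides 1 and 2, against the sign of its called members (camera adjusted p = 0.0476, and adjusted p = 0.881 with an estimated correlation). Its call ended with slide as a block (0.0581), under median centring (0.175), and without mutant replicate 3 (0.851) or wild-type replicate 2 (0.725).

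**Figure D3:**
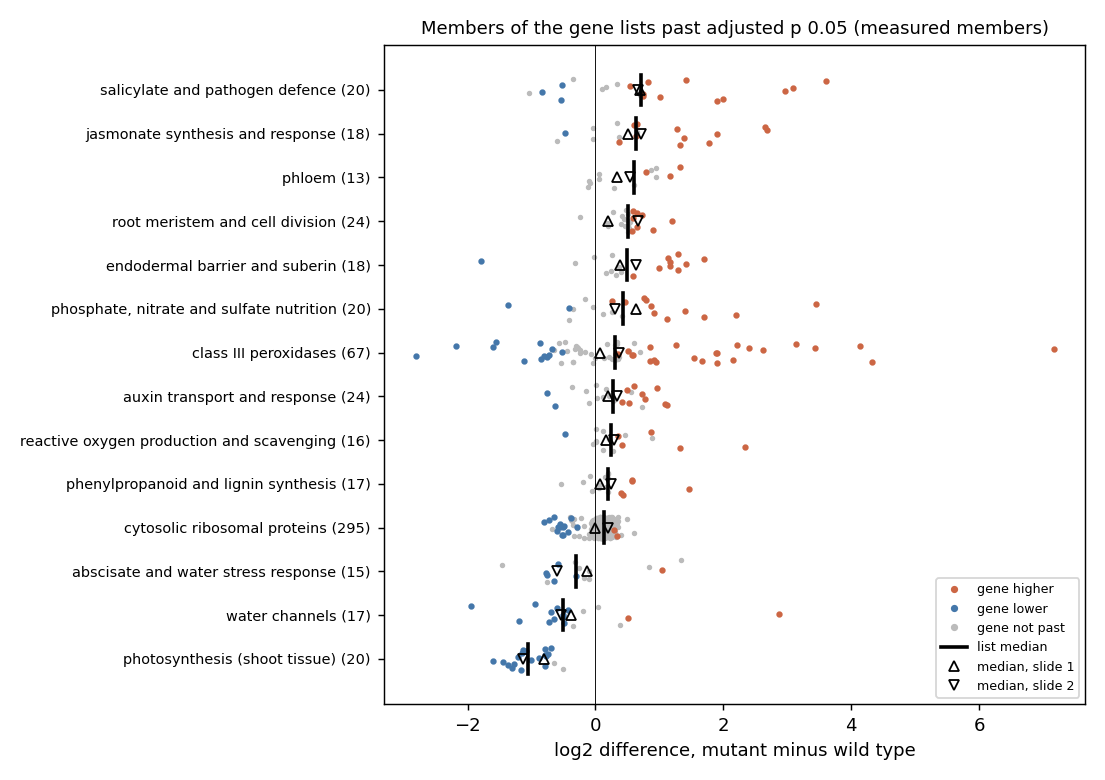
Log2 difference, mutant minus wild type (horizontal axis), of the measured members of the 14 lists past the camera threshold, with a bar for each list's median and triangles for its median on slide 1 and on slide 2. The photosynthesis list lies lowest with a median of -1.05, and the salicylate and defence list highest with a median of 0.72.

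Across the 33 lists, camera with its preset correlation called 14, fry called 12, and camera with an estimated correlation called 0, with 3 at an unadjusted p under 0.05. Fry did not call the root meristem (adjusted p = 0.0802), endodermal barrier (0.0975), abscisate (0.0901), phenylpropanoid (0.0541), phloem (0.187) or ribosomal (0.591) lists. It called lists that camera in the main fit did not: boron transport (0.00888), cytokinin (0.0487), expansins (0.0115) and glutathione S-transferases (0.00771). Without mutant replicate 2, camera called 9. The planned normexp fit was distorted on wild-type replicate 3 by an outlying local background. Under normexp as planned, the calls of the auxin (adjusted p = 0.108), salicylate and defence (0.267) and abscisate (0.117) lists ended. The boron transport (0.037), cytokinin (0.0272), expansin (0.000304) and glutathione S-transferase (0.000304) lists were called under normexp as planned. Of the 70 calls among named genes, 26 ended or turned there, among them AOC2 (0.23), PBS3 (0.54), AT1G14550 (0.52), ACS7 (1.25), PIP2;5 (1.26), GSTU11 (1.18) and BHLH100 (-1.88), all of which held with outlying local backgrounds replaced (1.21, 1.43, 1.59, 2.07, 2.105, 2.23 and -1.03), and IAA5 (-0.26), NAC101 (-0.31) and FLA5 (-0.26) changed sign. In that alternative, added after the data were seen, the 3 genes that changed sign stood at 0.58, 0.33 and 0.71, past no threshold, and 8 named calls ended in all. With unmoderated variances 14 ended, among them PBS3 (adjusted p = 0.0952), BHLH100 (0.0823) and AT3G47380 (0.0570).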

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

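The slide 2 arrays alone and normexp with outlying local backgrounds replaced were added after the data were seen. AXS2 kept its direction and call under all settings run, and AXS1 under all but the filter for all 6 arrays, which removed its probe. Of 70 calls among named genes, 40 held under all settings in which the gene was tested, and the others ended or turned in at least 1. The planned normexp correction gave 1100 genes higher and 1307 lower, and by at least 2-fold 293 higher and 370 lower. It turned NAC101 (-0.31), IAA5 (-0.26), FLA5 (-0.26), the boron transport median (-0.19) and the phloem median (-0.007). Among uncalled lists it also turned the medians of root cap (-0.037), pectin methylesterases (-0.19), polygalacturonases (-0.22), secondary wall (-0.077), cellulose (0.029) and heat shock proteins (-0.039). The boron transport median was below 0 under the other scalings too, quantile normalization (-0.071), median centring (-0.048), the authors' value table (-0.071) and repaired normexp (-0.033). The planned normexp ended or turned 26 of the 70 named calls, the repaired form 8 and unmoderated variances 14. It shifted the median of all genes to -0.14. On wild-type replicate 3 a local background of 73652.5, against a median of 26, pulled the fitted background mean to -872.7, and that array then correlated with the main values across probes at 0.892. With the 6 outlying backgrounds of that array replaced, the counts were 2042 and 2306, and 2-fold rises were still fewer at 540, for which the cause was not tested. Array weights gave 4974 higher and 4282 lower, unmoderated variances 1588 and 1583, and the cause was not tested. Leaving out 1 array left 1641 to 2972 genes higher and 1561 to 2911 lower, with fewer arrays in each fit, and 9 to 15 called lists. Camera with an estimated correlation called 0 lists, fry 12. The replicate block gave 3835 higher and 3593 lower, ended the calls of the peroxidase and phenylpropanoid lists, and changed no other call among the lists and named genes, with 5373 of the 5432 gene calls made there too. The scan block parts the arrays as the slide does. Signal over background limits genes dim in 1 group, such as PRX52, to a lower bound. That bound holds for the processed signal, and both forms of normexp gave a smaller fold for PRX52.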

Other observations

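The 2 tests of AXS2 copy number were chosen after the result was seen, as were the families grouped by symbol. Of 202 families with at least 8 measured members sharing a symbol stem, 24 passed camera at its preset correlation and 0 with an estimated correlation (4 at an unadjusted p under 0.05, each adjusted p 0.682 or higher). Not all 24 are described here. The lowest adjusted p was that of the light-harvesting LHCB family, lower in 7 of 9 members and higher in 0 (median -0.764, camera adjusted p = 0.000495). HCF genes were lower in 8 of 12 and higher in 0 (median -0.379, camera adjusted p = 0.00716). Sugar transporters of the SWEET family were lower in 6 of 11 members and higher in 1 (median -0.74, with -0.91 and -0.66 on slides 1 and 2, camera adjusted p = 0.0289). SWEET11 stood at -2.58 and SWEET12 at -1.99, both phloem-loading sucrose exporters in leaves, while SWEET14 stood at 3.48. Amino acid permeases were higher in 5 of 8 (median 0.81, with 0.33 and 0.91 on slides 1 and 2 and 0.52 under normexp as planned, camera adjusted p = 0.0154), with AAP3 at 1.43 and AAP1 at 1.03. CBL-interacting kinases were lower in 9 of 20 and higher in 1 (median -0.43, with -0.33 and -0.42 on the slides, camera adjusted p = 0.00716), with CIPK13 at -1.49. These directions held under each scaling alternative run.

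Glycerol-3-phosphate acyltransferases were higher in 5 of 9 (median 1.00, with 0.59 and 1.21 on slides 1 and 2, camera adjusted p = 0.0193), with GPAT1 at 1.73 and GPAT8 at 1.58. Ketoacyl-CoA synthases were higher in 6 of 14 (median 0.29, with 0.34 and 0.38 on the slides and 0.19 under median centring, camera adjusted p = 0.0333), with KCS3 at 2.27 and KCS17 at 2.07. The family holds KCS6 (CUT1, 1.20) and KCS10 (FDH, -0.006), which are also among the shoot genes outside photosynthesis described below. ABCG transporters were higher in 12 of 33 and lower in 1 (median 0.42, with 0.38 and 0.42 on the slides, but -0.037 under normexp as planned and 0.185 with outlying local backgrounds replaced, camera adjusted p = 0.00994). WOX homeobox genes were higher in 6 of 9 and lower in 1 (median 0.99, with 1.16 and 0.86 on the slides, but 0.082 under normexp as planned and 0.584 with outlying local backgrounds replaced, camera adjusted p = 0.0333), with WOX7, not well above background on any wild-type array, at least 5.74-fold higher, WOX4 at 1.28 and WOX2 at -1.36. Each of these families had an adjusted p of 0.682 with an estimated correlation.

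The AXS2 probe read 0.544 of the wild-type level (95% interval 0.472 to 0.628), with 0.469 on slide 1 and 0.587 on slide 2. The upper limit of 0.628 lies below 0.667, the ratio of an unsorted family of 1 wild type to 2 heterozygotes. This argues against such a mixture with a silent mutant allele only if the AXS2 probe reads no AXS1 transcripts. Otherwise the loss of AXS1 would lower the ratio too. The interval was computed under 1 scaling. A ratio of 0.5, as 1 silent copy of 2 would give, lies inside the interval, so 0.544 is consistent with the genotype in the labels as a hypothesis. Whether the AXS2 probe also reads AXS1 transcripts stays open: the longest stretch shared by the AXS1 and AXS2 probes is 5 bases, but the transcripts' sequences were not used here.

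The fall of the photosynthesis list may come from less shoot tissue at the cut end of mutant roots, from array quality, or from the genotype. Of 20 shoot genes outside photosynthesis listed before this test, 12 were measured, and 6 of them were higher and 0 lower. Their median was 0.997 (bootstrap 95% interval 0.149 to 1.29). The bootstrap drew from the 12 genes, so its interval measures the spread among them and not between pools. The median stayed above 0 under each scaling alternative, from 0.219 to 0.904, where less shoot tissue predicted -0.5 or lower. The rises were in LTP2 at 1.61, PDF1 at 1.50, LTP1 at 1.37, CUT1 at 1.20, CER1 at 1.11 and TCP4, of leaf development, at 0.95, while CER3 at 0.060, AS1 at 0.18 and FDH at -0.006 passed no threshold. None of these falls as less shoot tissue would have it. The bound was still wrong for a set with its own rises, which a lower share of shoot cannot give and which could hide it where roots express these genes. Outside the set, SWEET11 and SWEET12 fell and SWEET14 rose. Less shoot tissue therefore stays open. The list's median was highest at -0.811 over both slides and each array left out, which argues against 1 slide or array, and a response of root plastids to the genotype stays open and untested.

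MRD1 and HKT1 fell far more than most genes, which could reflect lost or linked sequence. Of the 4 measured neighbours of MRD1, HEI10 on 1 side was lowest at -1.581 (adjusted p = 0.000297), MSL4 and MUM4 stood at -0.42 and 0.33, and AT1G53460 at 0.096. A change reaching into HEI10 therefore stays open, while the neighbours of HKT1 ranged from -0.585 to 0.020. Near AXS1 and AXS2, 17 of 80 genes were called (21.2%) against 23.8% elsewhere (Fisher's exact test, two-sided, p = 0.693). That difference decides nothing. Of the 2 mutated loci, 0 lie on the chromosome of HKT1, a test chosen after the result was seen, which argues against sequence linked to them for HKT1. MRD1 shares its chromosome with AXS2 at a distance of 2764 measured genes, and the 4 measured neighbours of AXS2 were uncalled (-0.193 to 0.243). No test here set a bound on that distance. The labels give axs2-1 as heterozygous, so lost sequence linked to it would leave 1 of 2 copies, a ratio of about 0.5. MRD1 fell much further, by a log2 difference of -5.87 even under normexp as planned. That argues against lost sequence still carried with axs2-1 for MRD1. Lost sequence that has parted from axs2-1 over that distance could be in both copies and stays open, as does linked sequence that acts on both copies.

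The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 5432 genes and 1534 by at least 2-fold, and 1 of the 10 splits, the real one, gave as many; the highest other was 0 for both in limma. At an unadjusted p under 0.05 the real split gave 8511 genes and the others 52 to 1528. Each of the other splits mixes the genotypes, so genotype differences add to its spread within groups and lower its counts. The gene counts of the other splits are therefore no measure of chance. For called lists the real split gave 14, and 2 of the 10 splits, the real one included, gave as many, with the highest other at 15. That split, mutant replicate 1 with wild-type replicates 2 and 3, also parts all 3 replicate pairs, while 6 of the others part 1. Camera with its preset correlation thus called as many lists in a split with 0 called genes. Each other split keeps part of the genotype difference, so its called lists are no measure of chance either. With an estimated correlation, camera called 0 lists in the real split, so a list's call alone carries little weight here.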
